A study of Mus musculus with 8 samples.

How the data were processed

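RNA from 8 mouse retina samples, 4 control and 4 injected, had been hybridised to Affymetrix arrays, 1 array per sample. The groups were taken from the sample labels, which describe fresh retina for 1 group and injected retina for the other. The purpose of the injection is not stated in the labels.

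The deposited values are 1 linear intensity per probe set and array. The mean of each array after leaving out 2% of probe sets at each end is 2500 on all 8 arrays, as a global scaling by the authors to a common target gives; the software and its settings are not given in the sources used here. Such scaling fixes the mean level of every array, so a change in total RNA per retina cannot be seen. The deposited table held 45101 probe sets. The 64 array control probe sets were used only as quality measures, which left 45037. Of these, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none; only those with 1 symbol were named. Symbols were compared with a current reference through Entrez identifiers, 34754 matched and 0 changed. Genome coordinates are not given because the platform annotation names no build.

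The main design kept the deposited scaling unless array medians differed by over 1.5 times. The ratio of the highest to the lowest median was 1.55, so the deposited intensities were quantile-normalised between arrays in limma 3.58.1 (R 4.3.3) and transformed as log2(intensity + 16). Every log2 value and difference comes from these intensities deposited by the authors, and the added 16 understates the change of dim genes. Probe sets whose mean log2 value over all 8 arrays was at or above the 40th percentile were tested, a floor of about 345 intensity units (log2 value 8.5), which left 27022 probe sets and 12886 genes. Detection calls were not used here. Probe sets with names ending in x_at or s_at can bind related transcripts, and 7 of the 68 genes that the text takes from the rule below are read from such probe sets (among them Socs3, Gfap, H2-K1 and C1qb), so these are less certain. Crystallin and interferon-inducible GTPase families hold close copies as well.

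Injected was compared with control by limma (lmFit and eBayes, 3.3 prior degrees of freedom) with Benjamini-Hochberg adjustment and a threshold of 0.05. For gene lists, each gene was read at its probe set with the highest mean. A total of 29 lists with 655 different genes, for retinal cell types, cells that a dissection or an injection can bring in, and stress, immune and metabolic pathways, were fixed before the data were examined, as were the tests, the rule for naming genes and all alternatives except 2. Of these genes 481 were tested, and the 26 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Within each list p-values were also adjusted over the list alone. Exact two-sided permutation tests over the 70 assignments of 8 arrays to 2 groups of 4 used the list mean per array or an array quality value; their smallest p is 0.0286.

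Genes were named by a rule: those past the threshold with groups that do not overlap, and where fewer than 12 of a direction pass, the smallest p up to 6 as not passing; up to 4 genes of each list by smallest p; and a fixed set of cell markers. The text names some of the 123 genes the rule gave. Of the 40 named genes with at least 2 tested probe sets, 10 had one of opposite sign.

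The scripts were tested on 20 simulated data sets of 27022 probe sets with 200 changed, in which limma made 89.4 calls on average, 4.65 of them false. Camera called a list of 20 genes shifted by 0.6 log2 units in 20 of 20 sets and an unshifted list in 0. A call here was an unadjusted p under 0.05. The simulated genes varied independently, so these counts do not show how the preset correlation performs where genes of a list vary together.

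Alternatives were pseudocounts of 1 and 64, no filter, the deposited scaling, centring on array medians, a trended robust prior, array weights (with statmod 1.5.0), a replicate block, 1 probe set per gene, an unmoderated test and leaving out each array in turn. The 2 alternatives added after the data were seen were leaving out control replicate 2 and injected replicate 3 together, and the exact permutation test of list means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.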

Results

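Gene expression was measured in mouse retina on 8 Affymetrix whole-genome expression arrays, 1 sample per array. The control group was 4 freshly dissected retinas, labelled as time 0 d. The injected group was 4 retinas from eyes that had received an injection, labelled as a compound-based treatment. The labels name neither the compound nor its dose, route or interval, and no sham-injected group was part of the comparison, so the injection, the compound and the handling of the tissue act together in every difference given here. Nothing in the labels says whether the 4 retinas of a group came from separate animals, and p-values then measure the spread between these samples, which may in part be technical. Median intensity per array ran from 495 to 766 on the deposited scale, and the number of arrays limits the precision of every value.

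The comparison asks which genes and cell types of the retina differed after injection. Injected retinas had higher signal across lists of interferon-response, antigen-presentation, complement, microglia, gliosis and crystallin genes. They had lower signal across lists of cone, rod, ganglion cell, Müller glia, pigment epithelium, retinoid, immediate early and sterol synthesis genes. By limma's camera test, 6 of the 26 tested lists were higher and 8 were lower at an adjusted p under 0.05, and 12 passed in neither direction. These 14 calls assume a preset correlation of 0.01 between genes. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.134. Exact permutation of list means gave its smallest p for 7 lists, which over the 26 lists adjusts to 0.106. The number of arrays sets that smallest p, so lists could pass this test only if many reached it together.

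Of 27022 probe sets tested with limma, 0 were higher and 0 lower after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.102. At an unadjusted p under 0.05 there were 1889 probe sets (990 higher, 899 lower), or 6.99% against 5% expected with no difference. The 2 groups did not overlap at 1370 probe sets, or 5.07% against 2.86% by chance. The unmoderated test also gave 0 and 0, while limma with array weights gave 7 higher and 1 lower. Without injected replicate 4 the counts were 31 and 7. In simulated data of this size and spread per probe set, the same fit recovered 16.6% of probe sets changed by 1 log2 unit. At 2 log2 units it recovered 68.2%. The simulated probe sets varied independently, 200 were changed, and all arrays had equal spread. Real arrays did not (array weight 0.191 for injected replicate 3 against 1.83 for control replicate 4), so these shares may not hold for them.

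The genes with the smallest p among those higher did not pass the adjusted threshold. Gal, which encodes the neuropeptide galanin, had a log2 value of 8.86 ± 0.16 in control and 11.24 ± 0.57 in injected retina (SD, n = 4 each), a difference of 2.38 ± 0.28 (SE; adjusted p = 0.102). Next came Stat6, a transcription factor of interleukin 4 signalling, at 1.5 ± 0.19 (SE; adjusted p = 0.109), and Nlrc5, a transactivator of class I antigen-presentation genes, at 1.66 ± 0.21 (adjusted p = 0.109). Socs3, a feedback inhibitor of JAK and STAT signalling, differed by 1.41 ± 0.19, the endoribonuclease Endou by 1.38 ± 0.19 and Wfs1, a membrane protein of the endoplasmic reticulum, by 1.11 ± 0.17. With array weights the adjusted p was 0.0454 for Gal, Stat6, Nlrc5, Endou and Wfs1. Without injected replicate 4 it was 0.0247 for Gal, 0.0288 for Nlrc5, 0.0288 for Endou and 0.0396 for Socs3.

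The genes with the smallest p among those lower did not pass the adjusted threshold either. Nr4a3, an orphan nuclear receptor, had a log2 value of 10.65 ± 0.49 in control and 7.49 ± 1.12 in injected retina (SD, n = 4 each), a difference of -3.16 ± 0.51 (SE; adjusted p = 0.301). The MAP kinase phosphatases Dusp4 and Dusp1 differed by -1.47 ± 0.25 (adjusted p = 0.318) and -1.38 ± 0.26 (adjusted p = 0.343). Egr1, a zinc finger transcription factor, differed by -1.14 ± 0.20. Sh2d1a, a lymphocyte signalling adaptor, differed by -1.09 ± 0.19, and 4930423M02Rik by -1.66 ± 0.30. In each of these 12 genes, higher or lower, all 4 injected values lay on 1 side of all 4 control values. Choosing genes by smallest p favours this, so it adds no separate support. The control mean of Stat6 (log2 value 7.97) and the injected means of Nr4a3, Sh2d1a (8.23) and 4930423M02Rik (7.75) lay below the filter floor of 8.5, where signal is dim.

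**Figure D1:**
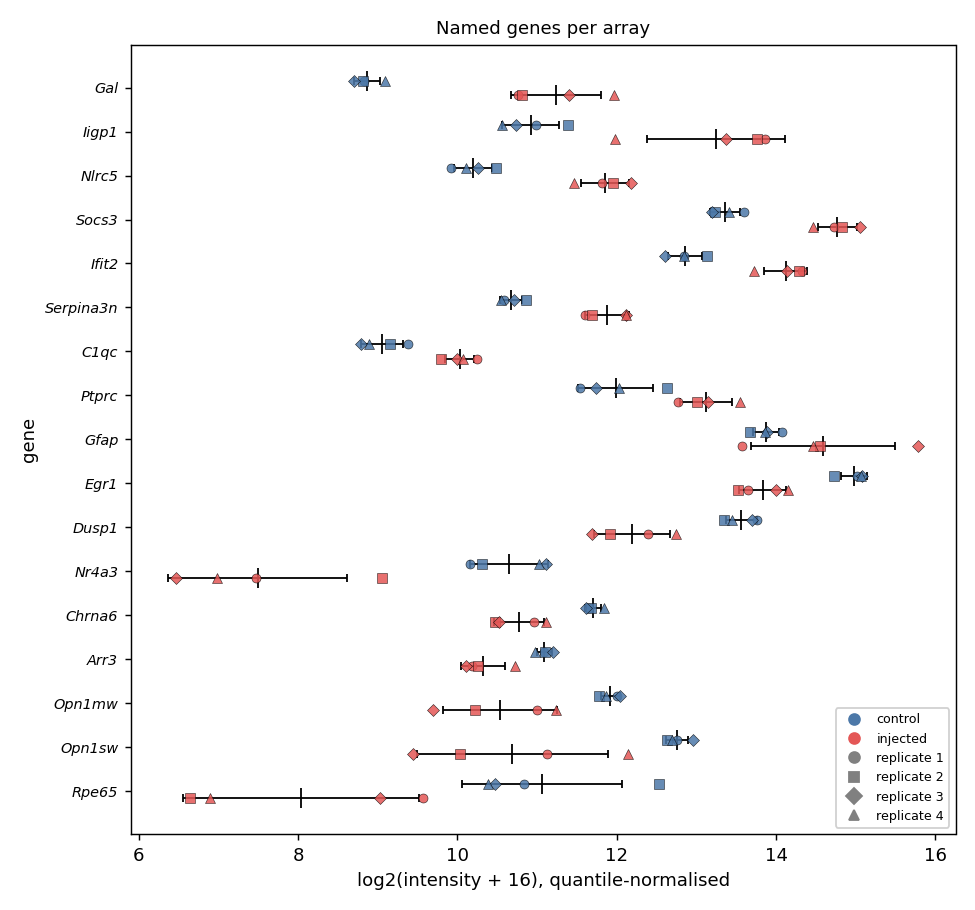
Log2(intensity + 16) after quantile normalization of 17 named genes (rows) on each of the 8 arrays. Marker shape gives the replicate number, whose meaning the labels do not give. The black tick and bar give the group mean and SD (n = 4). Gal lies at 8.86 in control and 11.24 in injected retina, and Nr4a3 at 10.65 and 7.49; none of the genes passed the adjusted threshold over all probe sets.

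The interferon-response list was higher in injected retina, with a mean log2 difference of 0.66 over 26 measured genes (camera adjusted p = 5.89e-13; adjusted p = 0.134 with an estimated correlation; exact two-sided permutation p = 0.0571). Adjusted over the list alone, 10 of its genes were higher, 0 were lower and 16 did not pass, against 0 over all probe sets. The antiviral genes Ifit2 and Rsad2 rose by 1.26 ± 0.21 and 1.18 ± 0.20 log2 units (SE) and Iigp1, an interferon-inducible GTPase, rose by 2.33 ± 0.41, as judged over the list alone. The 3 probe sets for Rsad2 ran from 0.21 to 2.26. Array means of the list were 0.66, 0.80, 0.99 and 0.18 above the control mean in injected replicates 1 to 4, and the highest control array, replicate 2, stood at 0.24. Without injected replicate 4, Iigp1 was at 2.75 and passed over all probe sets (adjusted p = 0.0131).

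The antigen-presentation list was higher by a mean of 0.73 over 13 measured genes, of which 3 are also in the interferon list (camera adjusted p = 4.42e-06; adjusted p = 0.134 with an estimated correlation; exact two-sided permutation p = 0.0571). All 13 differences were positive, 3 genes passed adjusted over the list alone and 0 over all probe sets. Those 3 were Nlrc5, the peptide transporter Tap1 at 1.05 ± 0.23 (SE) and the immunoproteasome subunit Psmb9 at 0.92 ± 0.28. H2-K1, a class I heavy chain, differed by 0.83 ± 0.31 and did not pass.

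The microglia and macrophage list was higher by 0.54 over 27 measured genes (camera adjusted p = 1.06e-07; adjusted p = 0.138 with an estimated correlation; exact two-sided permutation p = 0.0857). Adjusted over the list alone, 8 genes were higher and 19 did not pass, against 0 over all probe sets. They included the complement component C1qc at 0.97 ± 0.20 (SE), the leukocyte phosphatase Ptprc (CD45) at 1.13 ± 0.28, Ly86 at 0.69 ± 0.17 and the receptor Csf1r at 1.26 ± 0.35. Of 3 probe sets for Csf1r, 1 had the opposite sign (-0.26). Control replicate 2, which also had the highest signal of pigment-cell and matrix genes, stood 0.47 above the control mean of the microglia list, inside the range of the injected arrays (0.36 to 0.90).

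The complement list was higher by 0.53 over 9 measured genes, 3 of them shared with another list (camera adjusted p = 0.000225; adjusted p = 0.134 with an estimated correlation). Its mean lay above all controls in 4 of 4 injected arrays (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). C1qc and Cfi, a protease that inactivates complement, passed adjusted over the list alone, with Cfi at 0.75 ± 0.21 (SE), and 0 passed over all probe sets. C1qb at 1.32 ± 0.50 and Serping1, the C1 inhibitor, at 0.76 ± 0.29 did not pass, and C1qb was at 0.76 without injected replicate 3. With no filter on low signal the list mean was 0.35 (adjusted p = 0.00662).

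The reactive gliosis list was higher by 0.30 over 27 measured genes (camera adjusted p = 0.000642; adjusted p = 0.152 with an estimated correlation; exact two-sided permutation p = 0.0571). Adjusted over the list alone, 3 genes were higher and 24 did not pass, against 0 over all probe sets. The 3 were Socs3, the acute-phase protease inhibitor Serpina3n at 1.21 ± 0.20 (SE) and the vasoactive peptide Edn2 at 0.75 ± 0.20. A2m differed by 0.84 ± 0.26 and did not pass. Gfap, the intermediate filament of reactive Müller cells and astrocytes, differed by 0.72 ± 0.40 (adjusted p = 0.735), its groups overlapped, and without injected replicate 3 it was at 0.32. The 3 probe sets for Gfap ran from 0.09 to 0.72.

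The cone photoreceptor list was lower, with a mean log2 difference of -0.72 over 13 measured genes, all negative (camera adjusted p = 1.06e-07; adjusted p = 0.134 with an estimated correlation). All 4 injected arrays lay below all controls (exact two-sided permutation p = 0.0286). Adjusted over the list alone, 6 genes were lower and 7 did not pass, against 0 over all probe sets in the main setting. Another probe set for Arr3 passed over all probe sets with array weights (-1.48, adjusted p = 0.0454). It also passed without injected replicate 4 (-1.46, adjusted p = 0.0314), as did another for Opn1sw (-1.77, adjusted p = 0.0288). In the main setting the 3 probe sets for Arr3 ran from -1.52 to -0.77 and the 2 for Opn1sw from -2.07 to -1.46. The short-wavelength opsin Opn1sw fell by 2.07 ± 0.51 log2 units (SE), the medium-wavelength opsin Opn1mw fell by 1.39 ± 0.33, the channel subunit Kcne2 fell by 1.30 ± 0.33 and cone arrestin Arr3 fell by 0.77 ± 0.19, as judged over the list alone. Array means of the list were -0.50, -0.90, -1.11 and -0.38 against the control mean in injected replicates 1 to 4, and the 4 control arrays had an SD of 0.026.

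The rod photoreceptor list was lower by a smaller amount, at -0.31 over 24 measured genes (camera adjusted p = 0.00294; adjusted p = 0.258 with an estimated correlation). All 4 injected arrays lay below all controls (exact two-sided permutation p = 0.0286), and 0 genes passed adjusted over the list alone or over all probe sets. The endoplasmic reticulum protein Reep6 differed by -0.87 ± 0.25 (SE), rhodopsin kinase Grk1 by -2.10 ± 0.63 with its injected mean (7.79) below the filter floor, Samd7 by 0.68 ± 0.21 and the phosphodiesterase subunit Pde6b by -0.64 ± 0.24. Without injected replicate 2 the list mean was -0.27 and the adjusted p 0.0508.

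The retinal ganglion cell list was lower by a mean of -0.27 over 16 measured genes (camera adjusted p = 0.00247; adjusted p = 0.134 with an estimated correlation), with all 4 injected arrays below all controls (exact two-sided permutation p = 0.0286). Chrna6, a nicotinic receptor subunit, fell by 0.93 ± 0.20 log2 units (SE) adjusted over the list alone, the other 15 genes did not pass, and 0 passed over all probe sets. Sncg differed by -0.56 ± 0.25, and the ganglion cell markers Pou4f1 and Thy1 by -0.15 ± 0.18 and -0.09 ± 0.31, both within their SE. Pou4f1 was at -0.22 without control replicate 3, -0.08 without control replicate 4 and -0.10 without injected replicate 1. A second probe set for Pou4f1 was at -0.52. The difference of Thy1 turned positive without control replicate 2 (0.02) and without injected replicate 2 (0.13).

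The Müller glia list was lower by -0.30 over 21 measured genes, 2 of them in another list (camera adjusted p = 0.00495; adjusted p = 0.258 with an estimated correlation; exact two-sided permutation p = 0.114). No gene passed adjusted over the list alone (0 of 21) or over all probe sets (0). The carbonic anhydrase Car14 differed by -0.76 ± 0.21 (SE), Gpr37 by -0.93 ± 0.37, Crym by 0.42 ± 0.18, Dkk3 by -0.53 ± 0.26 and the retinaldehyde-binding protein Rlbp1 by -0.37 ± 0.20. Without injected replicate 3, Gpr37 was at -0.52 and Dkk3 at -0.31. Without control replicate 2 and injected replicate 3 together, a setting chosen after the values were seen, the list mean was -0.16 (adjusted p = 0.0365).

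The immediate early list was lower by -0.31 over 21 measured genes (camera adjusted p = 0.00819; adjusted p = 0.162 with an estimated correlation), with all 4 injected arrays below all controls (exact two-sided permutation p = 0.0286). Adjusted over the list alone, 5 genes were lower, 0 were higher and 16 did not pass, against 0 over all probe sets. Egr1 and Dusp1 were among the 5, with Egr3, which fell by 1.75 ± 0.39 log2 units (SE), and Fos, which fell by 0.78 ± 0.21. Leaving out injected replicate 1 (-0.27, adjusted p = 0.069) or injected replicate 4 (-0.29, adjusted p = 0.05) ended the call of the list.

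The pigment epithelium list had a mean difference of -0.85 over 17 measured genes, 5 of them in another list (camera adjusted p = 0.000413; adjusted p = 0.385 with an estimated correlation; exact two-sided permutation p = 0.171). The retinoid list had -0.49 over 17 genes, 7 of them in another list (camera adjusted p = 0.0128; adjusted p = 0.134 with an estimated correlation; exact two-sided permutation p = 0.0857). Rpe65, the isomerase of the visual cycle in pigment epithelium, fell by 3.02 ± 0.73 log2 units (SE) adjusted over either list alone, to an injected mean of 8.04, below the filter floor. The retinol dehydrogenase Rdh11 fell by 0.76 ± 0.17 adjusted over the retinoid list alone. No other gene of the 2 lists passed in this way, and 0 passed over all probe sets. The transthyretin gene Ttr, of the pigment epithelium list alone, differed by -0.88 ± 0.33 and Lrat, which esterifies retinol, by -1.18 ± 0.68. Control replicate 2 stood 1.5 above the control mean of the pigment epithelium list, and without it the list mean was -0.35 (adjusted p = 0.0856) and Lrat was at -0.68; without injected replicate 3, Lrat was at -1.78. Without injected replicate 2 the retinoid list was at -0.40 (adjusted p = 0.106).

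The crystallin list had the widest spread, with a mean difference of 1.78 over 10 measured genes, all positive (camera adjusted p = 0.000225; adjusted p = 0.312 with an estimated correlation; exact two-sided permutation p = 0.2). Crystallins are the abundant structural proteins of the lens, and some are also made in the retina. Crygf rose by 2.12 ± 0.53 log2 units (SE) adjusted over the list alone, the other 9 did not pass, and 0 passed over all probe sets. Crygd differed by 2.46 ± 0.99, Crybb2 by 3.08 ± 1.33 and Cryba1 by 3.48 ± 1.67, and the control means of Crygd (7.44) and Crybb2 (8.07) lay below the filter floor. Control arrays ran from -1.56 to 1.69 around their mean and injected arrays from 0.20 to 4.12, the last in injected replicate 2. The 3 measured lens genes other than crystallins were also highest on that array, at 1.15 above their control mean against at most 0.37 on any other. Without that array the mean difference was 1.01 (adjusted p = 0.0508) and Crybb2 was at 2.06, and without control replicate 2 Cryba1 was at 2.01.

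The sterol synthesis list was lower by -0.34 over 17 measured genes (camera adjusted p = 0.0146; adjusted p = 0.229 with an estimated correlation), with all 4 injected arrays below all controls (exact two-sided permutation p = 0.0286). No gene passed adjusted over the list alone (0 of 17) or over all probe sets (0). Insig1, a sterol sensor, differed by -1.04 ± 0.32 (SE), and the sterol oxidase Msmo1 by -1.56 ± 0.92. Injected replicate 3 lay at -0.80, and without it the list mean was -0.19 (adjusted p = 0.00851) and Msmo1 was at -0.45.

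**Figure D2:**
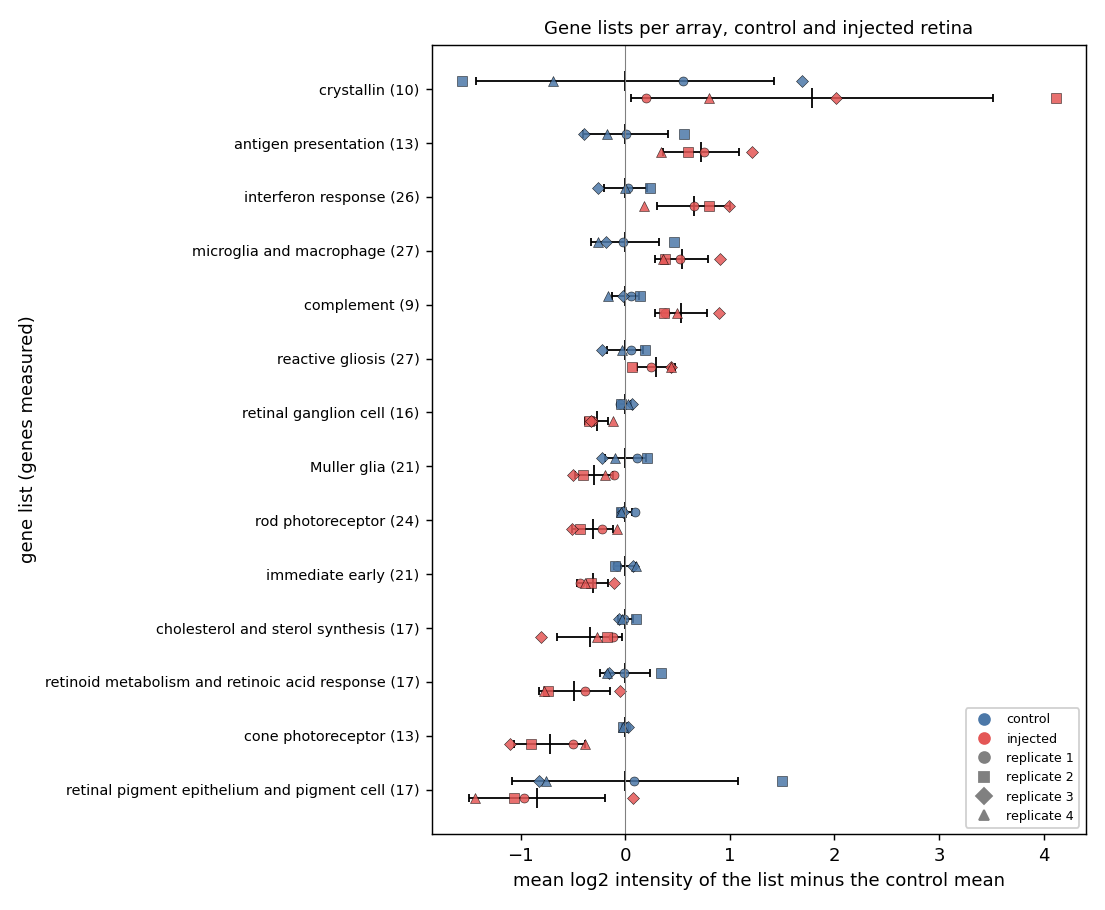
Mean log2 intensity of the 14 gene lists that passed the camera test, minus the control mean of each list, on each of the 8 arrays; the number of genes measured follows each name, marker shape gives the replicate number, and the black tick and bar give the group mean and SD (n = 4). The cone list lies between -0.38 and -1.11 in the injected arrays, below all controls, while crystallin and pigment epithelium genes spread widely within both groups.

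Lists for other retinal neurons did not pass. The amacrine and horizontal cell list differed by -0.05 over 18 genes (camera adjusted p = 0.335). Its genes went both ways, with Lhx1 at -1.20 ± 0.31 (SE), Onecut2 at 1.05 ± 0.30 and Calb1 at -0.61 ± 0.19. Gad1 was at -0.20 ± 0.17 (-0.12 without injected replicate 3), and a second probe set for Gad1 was at -0.82. The bipolar cell list differed by -0.21 over 18 genes (adjusted p = 0.0682), with Vsx1 at -0.61 ± 0.24 and Prkca at -0.25 ± 0.24, a second probe set for which was at 0.39; Prkca was at -0.09 without injected replicate 3 and at -0.41 without injected replicate 4. The synapse list differed by -0.09 over 24 genes (adjusted p = 0.335). On leaving out 1 array, the synapse list ran from -0.148 to -0.045 and the amacrine and horizontal cell list from -0.114 to -0.022. The p53 and apoptosis list differed by 0.25 over 14 genes (adjusted p = 0.0545), above all controls in 4 of 4 injected arrays (exact two-sided permutation p = 0.0286), with the caspases Casp12 at 1.36 ± 0.41 and Casp8 at 0.54 ± 0.18. It passed without control replicate 3 (0.26, adjusted p = 0.0375), without control replicate 4 (0.26, adjusted p = 0.0467) and without injected replicate 3 (0.27, adjusted p = 0.0191). With all arrays it passed with the values as deposited (0.34, adjusted p = 0.0193), with arrays centred on their medians (0.15, adjusted p = 0.0191) and with array weights (0.26, adjusted p = 0.0262). In the main setting its adjusted p = 0.162 with an estimated correlation. The bipolar list passed without control replicate 4 (-0.25, adjusted p = 0.0364) and without injected replicate 4 (-0.31, adjusted p = 0.0101). With all arrays it passed with no filter (-0.24, adjusted p = 0.0256), as deposited (-0.22, adjusted p = 0.0201), centred on medians (-0.41, adjusted p = 0.0233) and with a trended robust prior (-0.21, adjusted p = 0.0497). In the main setting its adjusted p = 0.385 with an estimated correlation.

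Lists of inflammatory mediators and of stress and metabolic genes did not pass either. The cytokine and chemokine list differed by 0.01 over 15 genes (camera adjusted p = 0.559) and heat shock and unfolded protein response by 0.05 over 25 genes (adjusted p = 0.263). Cell cycle differed by 0.13 over 21 genes (adjusted p = 0.137) and oxidative phosphorylation by -0.09 over 31 genes (adjusted p = 0.134). On leaving out 1 array, cell cycle ran from 0.05 to 0.203 and oxidative phosphorylation from -0.134 to -0.05. The NRF2 and antioxidant list differed by -0.20 over 19 genes (adjusted p = 0.137) and passed without control replicate 3 (-0.29, adjusted p = 0.0375) and without control replicate 4 (-0.27, adjusted p = 0.0467), with adjusted p = 0.469 with an estimated correlation and all arrays. Without control replicate 2 it was at -0.08 (adjusted p = 0.511). For tissue around the retina, the extracellular matrix and fibroblast list differed by -0.15 over 22 genes (adjusted p = 0.652), although the gelatinase Mmp2 rose by 1.90 ± 0.41 log2 units (SE) adjusted over the list alone. The endothelium and pericyte list differed by -0.14 over 16 genes (adjusted p = 0.306; -0.29 and adjusted p = 0.0401 without injected replicate 4; adjusted p = 0.628 with an estimated correlation and all arrays; -0.03 without control replicate 2 or without injected replicate 3), and cornea and conjunctiva by -0.16 over 10 genes (adjusted p = 0.306). Too few genes were measured to test lists of T cells and neutrophils (4 genes, mean difference -0.02, of which the neutrophil granule gene Ngp was at 1.09 ± 0.31 with its control mean below the filter floor), lens genes other than crystallins (3 genes, 0.18) and red blood cells (1 gene, -0.37).

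Array controls differed between the groups in 1 respect. The 3 prime over 5 prime signal ratio of Gapdh, a measure of RNA integrity and labelling, was 3.91 ± 0.57 in control and 6.76 ± 1.5 in injected retina (SD, n = 4 each), with all injected arrays above all controls (exact two-sided permutation p = 0.0286), so the ratio was higher in the same arrays as those in which the gene lists differed. The ratio of beta-actin was 47.0 ± 9.1 in control and 50.9 ± 6.9 in injected retina (SD, n = 4 each, exact two-sided permutation p = 0.543). On all 8 arrays, controls included, 3 prime signal exceeded 5 prime signal. The ratio ran from 3.36 to 8.82 for Gapdh and from 39.2 to 59.7 for beta-actin, so neither group was free of this bias. Injected replicate 3 stood apart from the rest. Its mean correlation with the other arrays was 0.869 against 0.927 to 0.942 for the others, and its spiked-in control signal was 2.43 times the control mean against at most 1.30 elsewhere. Without control replicate 2 and injected replicate 3 together, all 14 lists passed in the same direction at the preset correlation; with all arrays and an estimated correlation 0 passed.

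**Figure D3:**
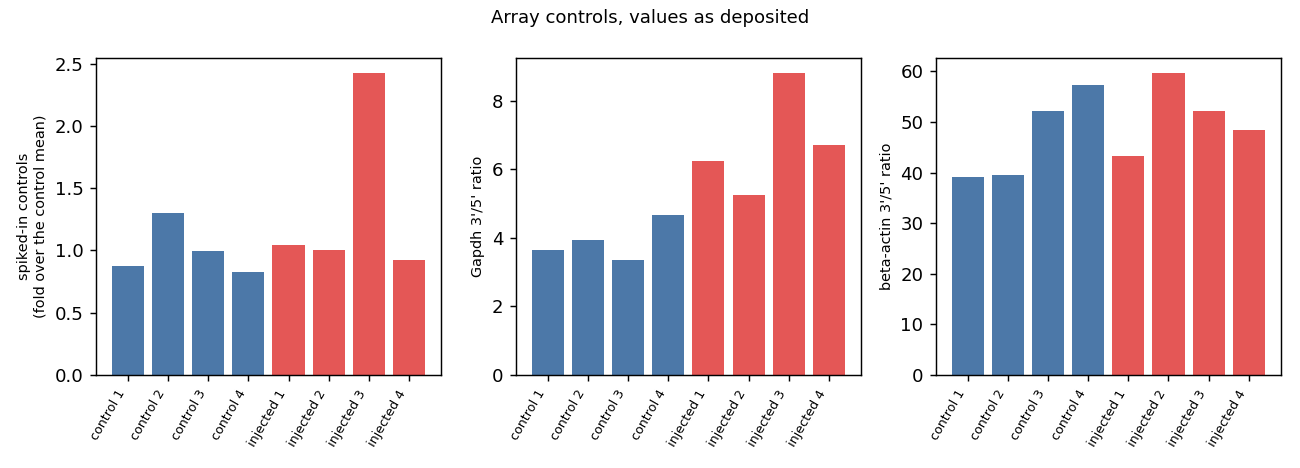
Spiked-in control signal as fold over the control mean (left), Gapdh 3 prime over 5 prime ratio (middle) and beta-actin 3 prime over 5 prime ratio (right) on each of the 8 arrays, 1 bar per array, from values as deposited. Injected replicate 3 has the highest spiked-in signal (2.43) and Gapdh ratio (8.82), and all 4 injected arrays exceed all controls in the Gapdh ratio.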

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

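The tests in this part were chosen after the results were seen, except the fits that leave out 1 array and the values as deposited, which were planned settings. Of 198 groups of 4 values examined, 9 had an array far from the others in its group (gap over range above Dixon's critical value), against about 10 expected by chance, so single cases carry little weight.

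In the injected group, replicate 3 lay far from the others in spiked-in control signal (2.43 times the control mean against a next value of 1.05; gap over range 0.92) and in mean correlation with the other arrays (0.869 against 0.927; 0.853). The first principal component held 39.4% of the variance, and this array made up 85.9% of it. The bacterial and phage spike-ins are added in fixed amounts and scaled with the rest of the array, so their 2.426-fold signal is consistent with less labelled retinal RNA on that array. More degraded RNA stays open: its Gapdh 3 prime over 5 prime ratio of 8.82 was above all other arrays, but its beta-actin ratio of 52.1 lay within their range. No biological explanation was tested. The 14 gene lists past the threshold also passed without this array at the preset correlation, while with all arrays and an estimated correlation 0 passed.

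Other values lay apart in 1 array. The endothelium and pericyte list was high in control replicate 2 (0.33 above the control mean; gap over range 0.838), the p53 and apoptosis list in injected replicate 2 (0.38; 0.832), and the rod list in control replicate 1 (0.10; 0.846). Endou was low in injected replicate 4 (log2 value 11.2; 0.836) and so was Sncg (9.34; 0.94). Ly86 was low in injected replicate 2 (13.0; 0.89), and Insig1 in injected replicate 3 (10.8; 0.863).

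The 4 immune lists (interferon, antigen presentation, complement, and microglia and macrophage) were higher in injected retina, by 0.60 ± 0.18 (mean log2 difference over their genes ± SE). Injected replicate 3 alone is argued against as the source, since the difference without it was 0.488 ± 0.157. Carry-over of pigment epithelium, choroid or sclera into the injected samples stays open: the pigment epithelium list was at -0.847 ± 0.629 but at -0.35 ± 0.44 without control replicate 2, and the matrix list at -0.15 ± 0.30 and 0.12 ± 0.17, while the immune genes without that array were at 0.72 ± 0.14. RNA integrity, read from the 3 prime over 5 prime ratio of Gapdh, cannot be told apart from the injection, because the ratio was above all controls in 4 of 4 injected arrays and 4 arrays are too few to test a trend within the group, where replicates 1 to 4 had ratios of 6.23, 5.26, 8.82 and 6.71 with interferon shifts of 0.66, 0.80, 0.99 and 0.18. The injection itself, the compound and the interval after injection stay open as biological differences that the design does not separate.

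The cone list was lower in injected retina, by -0.72 ± 0.17. A smaller share of all retinal neurons is argued against as the whole of it, since the cone list fell beyond the amacrine and horizontal cell list (by -0.668 ± 0.126), the rod list (-0.41 ± 0.08), the ganglion cell list (-0.45 ± 0.14) and the bipolar list (-0.51 ± 0.10), each in 4 of 4 injected arrays; a part stays open, as the rod (-0.31), ganglion cell (-0.27) and bipolar (-0.21) lists were also negative. Injected replicate 3 alone and the scaling between arrays are argued against too, since the difference was -0.592 ± 0.158 without that array and -0.711 ± 0.174 with the values as deposited. RNA integrity, read from the 3 prime over 5 prime ratio of Gapdh, again cannot be told apart from the injection (above all controls in 4 of 4 injected arrays); the replicate with the highest ratio, 3, had the largest cone shift (-1.11), while replicates 1, 2 and 4 had -0.50, -0.90 and -0.38. Fewer cones and less RNA of these genes per cone were not distinguished by any test.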

How the results depend on the processing

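The 2 settings added after the data were seen are the pair of arrays left out together and the exact permutation of list means. Probe sets past the threshold numbered 0 and 0 in limma (1889 at an unadjusted p under 0.05), 7 higher and 1 lower with array weights, and 0 to 31 higher and 0 to 7 lower on leaving out 1 array, where only the fit without injected replicate 4 gave calls. Array weights and that fit shared 6 probe sets. All other settings gave 0, and the cause was not tested. Of the 35 splits of the 8 arrays into 4 and 4, all 35 had to give at least as many probe sets past the threshold, since the real count is 0 (highest other 1), so that count decides nothing; at an unadjusted p under 0.05 the real split gave the most (1889, highest other 1862). For lists, 1 of 35 splits gave as many (real 14, highest other 11), the smallest share possible here. The other splits, balanced or not, called a median of 4 lists. Those that balance the groups called 0 to 7 (7 for control replicates 1 and 2 with injected 1 and 4). Calls at the preset correlation thus also arise without a group contrast. The rank of the real split argues against chance only as far as 1 in 35 can, for calls at that correlation, and does not exclude it. The interferon mean was as large in 2 splits, the real one (0.66) and the exchange of control replicate 2 with injected replicate 4 (0.69). The cone mean was as large in 1 split, the real one.

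Lists past the threshold numbered 6 higher and 8 lower. They were 0 and 0 by camera with an estimated correlation, 1 and 1 by fry (complement and ganglion cell), and 0 and 0 by exact permutation, whose smallest adjusted p is 0.106. Estimated correlations of the 14 lists ran from -0.031 (complement) to 0.75 (crystallin), and complement, ganglion cell (-0.022) and retinoid genes (0.006) lost their call with an estimate below the preset value, so a higher correlation does not account for those; in that setting camera also takes its degrees of freedom from the arrays, which are few, and not from the genes. On leaving out 1 array the 14 lists passed in 106 of 112 fits, all in the same direction. The 6 exceptions were pigment epithelium without control replicate 2 (adjusted p = 0.0856), immediate early without injected replicate 1 (0.069) or 4 (0.05), and crystallin (0.0508), rod (0.0508) and retinoid (0.106) without injected replicate 2. Centring arrays on their medians moved the median difference of all tested probe sets to -0.15 (from -0.02). List means moved with it, to 0.133 for gliosis, -0.493 for rod, -0.451 for ganglion cell, -0.453 for Müller glia and -0.474 for immediate early genes. Relative to that median difference the cone list was at -0.74 and gliosis at 0.29. Same-numbered samples did not deviate together (correlations 0.08, 0.01, -0.03 and 0.04, with 2 of 8 samples correlating best with their own number). With 4 samples per group this cannot show whether the numbers pair samples, and the labels do not say what they mark. With a replicate block the counts were 0 and 0 probe sets and 7 and 8 lists. The added list was p53 (0.246, adjusted p = 0.0354), which also passed without control replicate 2 and injected replicate 3 (0.25, adjusted p = 0.0413).

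Values that changed sign were near 0. With median centring and with array weights, cytokine genes were at -0.066 and -0.054 and heat shock at -0.10 and -0.029. Over the alternative processing settings with all arrays kept, the cytokine list ran from -0.066 to 0.269. Without control replicate 2 and injected replicate 3, cytokine was at -0.096, heat shock at -0.02, endothelium at 0.081 and matrix at 0.047. On leaving out 1 array, cytokine ran from -0.068 to 0.124, heat shock from -0.031 to 0.105, cornea from -0.349 to 0.041 and matrix from -0.305 to 0.115; Thy1 ran from -0.331 to 0.13, with 0.022 without control replicate 2. Of 1292 values of named genes under alternatives, 1280 kept direction and side of the threshold, 10 passed it and 2 changed sign. Leaving out 1 array moved 12 of 68 named genes by over 1.5 times, none of them past the threshold. Dim signal limits 9 named genes with a group mean below the filter floor (Stat6, Nr4a3, Sh2d1a, 4930423M02Rik, Rpe65, Ngp, Grk1, Crygd and Crybb2).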

Other observations

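The test in this part was set before its genes were looked at, prompted by the higher Socs3 signal. Socs3, Serpina3n and A2m are known targets of JAK and STAT3 signalling, the path used by cytokines of the interleukin 6 family. A hypothesis is that this signalling was higher in injected retina. A further list of 23 genes linked to this signalling, of which 18 were measured, had a mean log2 difference of 0.43, and 15 differences were positive. Its limma camera p was 0.000171, and the exact two-sided permutation p of the list mean was 0.0571. Beside targets, the list holds members of the path itself (Jak2, Lifr and Il6st). It is thus not a set of STAT3 targets alone and does not separate STAT3 from other STAT proteins. With an estimated correlation the camera p was 0.0337. These camera p-values are unadjusted, so they cannot be set beside the adjusted values given for the other lists. In this list 0 genes passed adjusted over the list alone or over all probe sets. The smallest p belonged to the metalloreductase Steap4, at 1.20 ± 0.36 (SE), then to the acute-phase gene Saa3, at 2.37 ± 0.86. These genes were chosen after the higher Socs3 was seen and interferons also use STAT proteins, so the camera p of 0.000171 may reflect either path, and the injection was not separated from the compound.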
